A study of Homo sapiens with 8 samples.

How the data were processed

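The series holds 8 samples of PC9 cells, 1 per group. H3K9me3 ChIP was done in parental cells, in cells kept in 1 uM erlotinib for 8 days (DTP), and in such cells with 50 nM TSA for 5 hours (DTP + TSA). The other samples are 2 H3K4me3 libraries and 3 input libraries, which were not analysed here. Chromatin was sheared to 300 to 500 bp and reads were 150 bp, per the labels' protocols.

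Each H3K9me3 library has a deposited list of enriched intervals with chromosome, start, end, summit position, summit value, mean value and number of bins, per the file headers. BWA, SICER and the builds hg19 and dm3 are named without versions or roles, per the submitters' processing notes. Which input was used, the calling threshold and any scaling between libraries are not given in the sources used here. The summit value and the mean value are the authors' signal within each interval, per the file headers. They are the authors' own and served only to describe, rank and filter intervals within a library. The mean value times the number of bins was a whole number for 100% of intervals in each list, within rounding of the printed digits. All starts and ends lay on a grid of 200 bp, with ends given as the last base of a step, and no gap between neighbouring intervals was below 800 bp. The smallest mean signal was 3.55 in parental cells, 3.55 in DTP and 3.59 in DTP + TSA. No interval passed an hg19 chromosome end. The lists carry no read totals, so depth is unknown. A deeper library or a different threshold can change the number and the lengths of intervals, which bears on every count and covered length.

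Covered length was computed on the grid of 200 bp. An interval was shared when it overlapped the other library by at least 1 bp. Expected overlap was the mean of 100 random rotations of the other library along each chromosome, and of 100 shifts by 100 kb to 1 Mb. Shares have exact Clopper-Pearson 95% intervals. Coordinates are 1-based on hg19. Band borders and stains came from the hg19 cytoband table in circlize 0.4.16, and chromosome lengths from GenomeInfoDb 1.38.1, under R 4.3.3. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The code was tested on 5000 intervals sampled from the DTP list and on other inputs built to have known answers. Of 9 checks, 9 returned the known answer within a set tolerance.

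No hg19 gene annotation was used here, so the planned test of gene bodies was replaced. Genes of a GRCh38 table were placed in GRCh38 bands, and coverage was measured in the hg19 band of the same name; all 862 hg19 band names had a match, and 59665 of 59792 genes were placed. A list's value is the mean coverage of its genes' bands, set against 10000 random sets of bands matched on band length in 5 classes and carrying the same weights. The sets were drawn from all 862 bands, some of them without coverage in any library. They were not matched on gene density or on starting coverage. A high or low percentile therefore need not be particular to a list. The 15 lists were fixed before the data were examined, as were the overlap rule, the alternatives and the rule naming the 3 longest intervals found in 1 library of each comparison. The rule for single named genes needed gene positions and was not applied, nor were planned values for single control genes. Bands, 1-Mb windows, the 6 kb length class and distances to chromosome ends were examined after the data had been seen.

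Alternatives were an overlap of at least 50% of the interval, reciprocal overlap of at least 50%, joining of intervals within 5 kb, the upper part of each library split at its median mean signal, the 23842 strongest intervals of each library, removal of intervals below the pooled median length of 2600 bp, autosomes alone, and a length-weighted mean of signal. Ranking by summit height, removal of centromeric, variable and stalk bands, and removal of 19p12 were chosen after seeing the data. GC content was not examined, since no genome sequence was used here.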

Results

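H3K9me3, the histone mark of constitutive heterochromatin, was profiled by ChIP-seq in PC9 cells, an established line of human lung adenocarcinoma that carries an activating EGFR mutation and dies in EGFR inhibitors. 3 states were compared. Parental cells were untreated, drug-tolerant persisters (DTP) were the cells that survived 1 uM erlotinib, an EGFR kinase inhibitor, for 8 days, and DTP + TSA were such persisters given 50 nM trichostatin A, an inhibitor of histone deacetylases, for 5 hours. Each state had 1 H3K9me3 library with a deposited list of enriched intervals on hg19. With 1 library per state no difference has a replicate check, and no p-value is given. Shares carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. The read depth of the libraries is unknown from the lists.

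The persister library held more and shorter H3K9me3 intervals than the parental one, and fewer long domains. The parental list had 23842 intervals over 125 Mb (4.05% of hg19), the DTP list 47866 over 165 Mb (5.32%) and the DTP + TSA list 53000 over 179 Mb (5.79%). DTP therefore had 2.01 times as many intervals and 1.32 times the covered length of parental cells. Median length was 3800 bp in parental cells and 2400 bp in each of the other libraries. Intervals of up to 2 kb made up 16.5% of the parental list, 38.5% of the DTP list and 41.9% of the DTP + TSA list. Domains over 16 kb went the other way, from 671 with 22.9 Mb in parental cells to 395 with 12.2 Mb in DTP, and stood at 613 with 17.1 Mb after TSA. With the 23842 strongest intervals of each library by mean signal, DTP covered 0.71 times the parental length, near the 0.66 that an equal number of intervals at the mean lengths of the full lists gives.

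A class of intervals close to 6 kb was most frequent in DTP. Intervals of 5.8 to 6.2 kb numbered 2252 in DTP against 1581 of 4.8 to 5.2 kb, a ratio of 1.42 (95% interval 1.34 to 1.52). The same ratio was 0.69 (0.64 to 0.75) in parental cells, with 1072 and 1552 intervals, and 1.07 (1.00 to 1.14) in DTP + TSA, with 1762 and 1653. With intervals within 5 kb joined it was 1.82 in DTP, 1.65 (1.54 to 1.78) in DTP + TSA and 0.69 in parental cells. Without joining, DTP + TSA also had a local maximum at 6000 bp, with 484 intervals at 5600 bp and 639 at 6000 bp. Lengths of exactly 6000 bp occurred 332 times in parental cells, 895 times in DTP and 639 times in DTP + TSA. These were 1.39%, 1.87% and 1.21% of the lists, which differ in size. The whole class of 5.8 to 6.2 kb made up 4.50%, 4.70% and 3.32%. In DTP, 32.4% (30.5 to 34.4) of the 6 kb class lay in the dark Giemsa bands (gpos75 and gpos100), gene-poor and AT-rich parts of the chromosomes, against 23.5% (21.9 to 25.1) of the intervals of flanking lengths (4.8 to 5.2 and 6.8 to 7.2 kb). In DTP + TSA these shares were 22.2% (20.3 to 24.2) and 14.8% (13.5 to 16.2). The DTP class overlapped parental intervals less often than flanking lengths did, at 42.2% (40.1 to 44.3) against 53.6% (51.7 to 55.5). This length class was defined after the distribution of lengths had been seen.

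**Figure D1:**
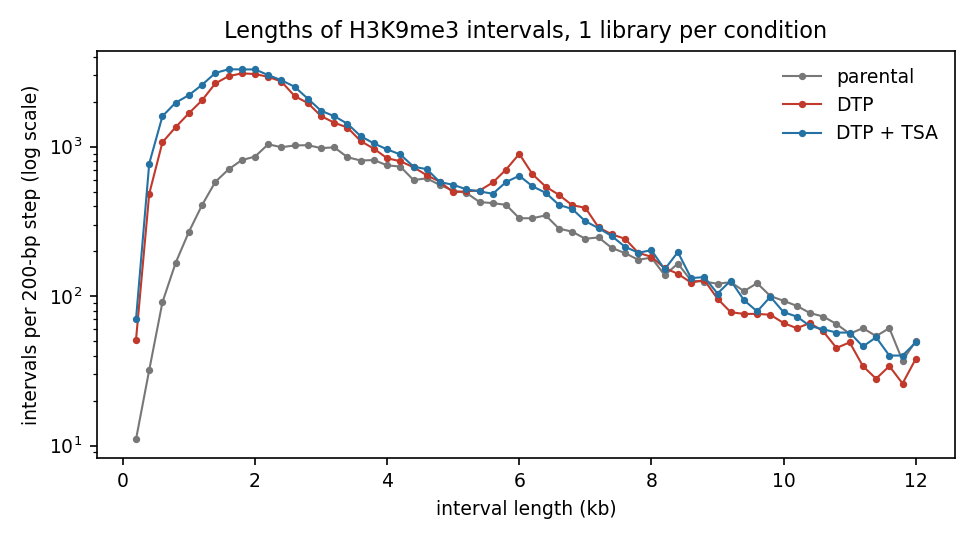
Number of H3K9me3 intervals (vertical axis, log scale) at each length up to 12 kb in steps of 200 bp (horizontal axis) in the parental, DTP and DTP + TSA libraries, 1 library per state. The DTP line has a local maximum of 895 intervals at 6 kb and the DTP + TSA line a lower one of 639. The parental line, at 332, has none there.

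The first comparison asked how the heterochromatin of persisters differs from that of the cells they came from. Most of the DTP intervals were absent from parental cells, and about equal lengths of parental H3K9me3 were kept and lost. Of the 23842 parental intervals, 15290 or 64.1% (63.5 to 64.7) overlapped a DTP interval by at least 1 bp, and of the 47866 DTP intervals 16378 or 34.2% (33.8 to 34.6) overlapped a parental one. In covered length, 63.0 Mb was shared, 62.3 Mb was in parental cells and not in DTP, and 102 Mb in DTP and not in parental cells. Random rotation of 1 library along each chromosome gave overlaps of 12.7% and 6.86%, and shifts of 100 kb to 1 Mb, which keep the regional density, gave 15.9% and 9.04%. Kept parental intervals had a median length of 4000 bp and a median mean signal of 9.03, lost ones 3400 bp and 7.11. DTP intervals shared with parental cells had a median of 3400 bp and a signal of 12.3, those absent from parental cells 2200 bp and 9.67.

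The DTP gain was broad, and chromosome X and chromosome 4 had the largest increases. Covered length was higher in DTP on 23 of 24 chromosomes. Chromosome X went from 1.73% to 4.42% covered, 2.56 times the parental length, and chromosome 4 from 2.14% to 4.43%, 2.07 times. Chromosome 19, the chromosome with by far the highest coverage in every library, was the exception at 21.0% in parental cells and 19.96% in DTP. By Giemsa stain, the darkest bands (gpos100) rose 1.57 times and the centromeric bands (acen) 1.86 times. The other dark bands (gpos75) and the light bands (gneg) each rose 1.31 times. The variable bands (gvar) stood at 0.70 times the parental covered length, a fall carried by 19p12, since the other 16 went from 0.71 to 0.81 Mb. With equal numbers of the strongest intervals by mean signal the ratios were 0.93 on X, 0.82 on chromosome 4 and 0.62 on chromosome 19. Over all chromosomes the ratio was then 0.71, with X and chromosome 4 above it and chromosome 19 below it. The other chromosomes were not computed singly under this setting. Chromosome 19 was above parental without 19p12 (1.11), with intervals within 5 kb joined (1.03) and without centromeric, variable and stalk bands (1.09).

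**Figure D2:**
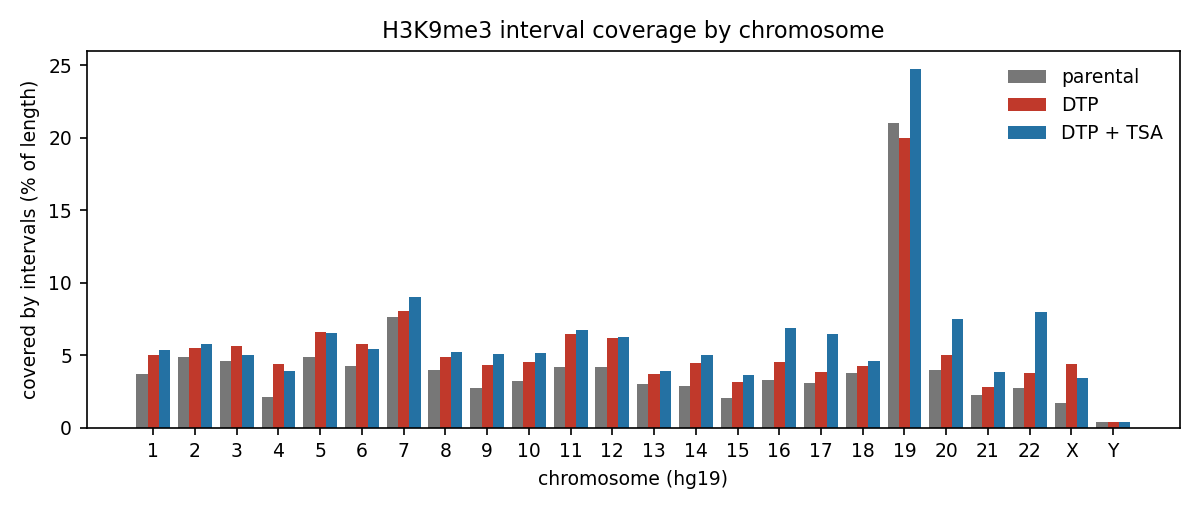
Percent of each hg19 chromosome covered by H3K9me3 intervals (vertical axis) in the parental, DTP and DTP + TSA libraries, 1 bar per library. Chromosome 19 is covered at 21.0%, 19.96% and 24.7%, and chromosome X at 1.73%, 4.42% and 3.41%.

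Of 822 bands of at least 1 Mb, 665 were covered more in DTP than in parental cells and 125 less. The largest losses were in 19p12, a zinc finger gene cluster that fell from 90.2% to 55.6% covered, 8q24.21, the band of MYC, from 25.8% to 7.80%, 7p11.2 from 40.2% to 24.5%, 3q28 from 22.3% to 7.28%, and 6p24.1 from 18.9% to 7.71%. The largest gains were in 7p22.3, from 9.16% to 24.2%, and Xp11.21, from 3.45% to 18.1%. The next 3 gains lay in the centromeric bands 19q11 and 12p11.1, and in 11p11.12 beside a centromeric band. Coverage there rose from 8.37%, 7.58% and 18.9% to 19.4%, 17.6% and 28.7%. The named bands were chosen by the size of their change after their values were seen. With equal numbers of the strongest intervals by mean signal, a setting that lowers the covered length of DTP as a whole, 7p22.3 and Xp11.21 were still gained, the latter at 1.94 against 5.23 with all intervals and 15.8 in the upper part of each library by mean signal. With equal numbers by mean signal the bands in or beside centromeres were at 0.85 in 19q11, 0.76 in 12p11.1 and 0.43 in 11p11.12. Equal numbers by summit height left them at 1.87, 1.11 and 1.23, and the upper part by mean signal at 1.97, 3.58 and 1.23.

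The 3 longest parental intervals absent from DTP lay at chr7:56450001-56493200 in 7p11.2 (43.2 kb), chr2:173083401-173119800 in 2q31.1 (36.4 kb) and chr3:189008001-189042000 in 3q28 (34.0 kb), all on hg19. The 3 longest DTP intervals absent from parental cells lay at chr16:1089201-1121000 in 16p13.3 (31.8 kb), chr5:473601-505200 in 5p15.33 (31.6 kb) and chr11:50655001-50680200 in 11p11.12 (25.2 kb). The 1-Mb window around the 3q28 interval, chr3:189000001-190000000, went from 66.0% covered in parental cells to 10.3% in DTP and 8.90% in DTP + TSA. On chromosome 8, the window chr8:128000001-129000000 went from 36.7% to 6.64% and 5.54%.

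Bands rich in C2H2 zinc finger genes, most of which encode KRAB-type repressors, were the most heavily marked of the gene families, and one of them, 19p12, lost much of its coverage in DTP. Genes were assigned to bands, and each list's coverage is the mean over its genes of the coverage of the band each lies in, so it describes the surroundings of the genes and not the genes themselves. For 563 zinc finger genes in 161 bands it was 23.3% in parental cells, 21.2% in DTP and 24.6% in DTP + TSA, above all 10000 random sets of bands of matched length in each library. The change from parental to DTP was -2.14 points, below all random sets. Without 19p12, which holds 37 of the genes, the change for the other 526 was 0.15 points, still low among random sets at percentile 0.89. Their bands began at 18.6% in parental cells, and random sets were not matched on starting coverage. DTP over parental was 1.89 in 1-Mb windows under 5% mean coverage over the 3 libraries and 1.16 at 5% to 20%. The low ranks therefore need not be particular to zinc finger genes. On chromosome 19 the 6 bands with at least 20 zinc finger genes went from 47.2% covered to 38.6% and 41.7%, and without 19p12 from 35.9% to 34.1% and 38.2%, while the other 13 bands went from 6.56% to 9.68% and 15.4%. Besides 19p12, 19q13.12 fell from 53.0% to 42.8%, 19q13.31 from 27.6% to 22.2%, 19q13.41 from 55.7% to 51.6% and 19q13.43 from 44.4% to 43.3%, whereas 19p13.2 rose from 21.4% to 24.4%.

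**Figure D3:**
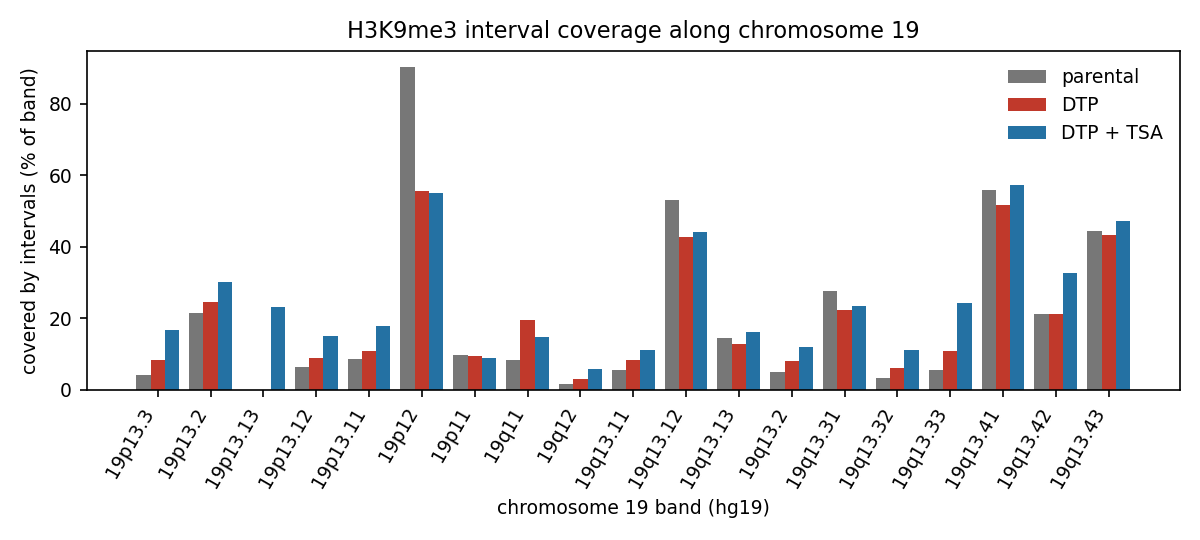
Percent of each chromosome 19 band covered by H3K9me3 intervals (vertical axis) in the parental, DTP and DTP + TSA libraries, 1 bar per library, in order along hg19. 19p12 falls from 90.2% in parental cells to 55.6% in DTP and 54.9% after TSA.

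The other gene families differed in direction, and most stood within the range of random bands. The bands of 864 genes with olfactory receptor names, a list that takes in pseudogenes, went from 4.45% to 7.00% and to 7.71% with TSA. The change from parental to DTP stood at percentile 99.5 of random sets. With equal numbers of the strongest intervals this change stood at percentile 31.0, so its place against random bands depends on the weaker intervals. For 127 cancer-testis antigen genes, germline genes mostly on chromosome X, coverage was 2.34%, 4.54% and 4.21%. The band of the 54 clustered protocadherin genes, 5q31.3, was at 7.97%, 7.72% and 7.97%, and with equal numbers of the strongest intervals it changed by -2.89 points from parental to DTP. The 4 bands of the HOX clusters were at 5.71%, 6.86% and 7.94%, and the bands of 93 histone genes at 4.63%, 5.29% and 6.08%, with changes from parental to DTP at percentiles 36.8 and 25.6.

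The shorter lists served mainly to show where ordinary genes stood. Bands of 20 housekeeping genes, taken as a negative control, were at 5.67%, 7.81% and 10.9% in parental, DTP and DTP + TSA. Their change from parental to DTP stood at percentile 95.3 and that under TSA at percentile 99.6. High percentiles thus also arose for ordinary genes. Against that background, genes of the EGFR pathway and bypass receptors were at 6.04%, 6.91% and 8.91%, genes of the H3K9 methylation machinery at 5.86%, 7.81% and 10.0%, and histone demethylases and deacetylases at 5.31%, 6.75% and 9.73%. Imprinted genes were at 7.44%, 8.99% and 12.8%, and nucleic acid sensing and interferon genes at 3.30%, 5.42% and 7.32%. Lung epithelial genes were at 3.46%, 5.23% and 6.74%, and genes of other lineages at 4.04%, 5.78% and 7.58%. Very long neuronal genes lay in the least covered bands, at 2.20%, 3.33% and 3.12%, at percentile 0.36 in parental cells and 0.10 in each of the other libraries.

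The second comparison asked what 5 hours of TSA changed in persisters. The total moved little, while coverage was higher in light bands and toward chromosome ends and lower in dark bands and the interior of chromosomes. DTP + TSA had 1.11 times as many intervals as DTP and 1.09 times the covered length. Of the 47866 DTP intervals 34263 or 71.6% (71.2 to 72.0) overlapped DTP + TSA, and of the 53000 DTP + TSA intervals 35118 or 66.3% (65.9 to 66.7) overlapped DTP, against 11.4% and 10.5% under random rotation and 14.3% and 13.2% under local shifts. Covered length was shared over 114 Mb, present in DTP and not in DTP + TSA over 51.2 Mb, and the reverse over 65.5 Mb.

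Within 2 Mb of a chromosome end coverage went from 13.3% in DTP to 23.3% in DTP + TSA (1.75 times), and from 2 to 5 Mb from 7.38% to 15.8% (2.13 times). It was 1.36 times higher from 5 to 10 Mb and 1.09 times higher from 10 to 20 Mb, and beyond 20 Mb it was 0.90 times that of DTP. With equal numbers of the strongest intervals the ratio within 5 Mb of an end was 1.79, although the covered length over all chromosomes was then 0.96 times that of DTP. The proximal parts of chromosome Y and of the acrocentric chromosomes were left out. Of the 822 bands only 315 were covered more after TSA and 471 less, so the net gain came from a minority of bands. The largest gains were in 22q13.32, from 13.4% to 49.4%, 22q13.33, from 18.6% to 48.6%, 9q34.3, from 12.8% to 36.8%, 1p36.32, from 14.4% to 37.7%, and 5p15.33, from 16.8% to 37.1%. The distance classes and these bands were chosen after the data had been seen.

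**Figure D4:**
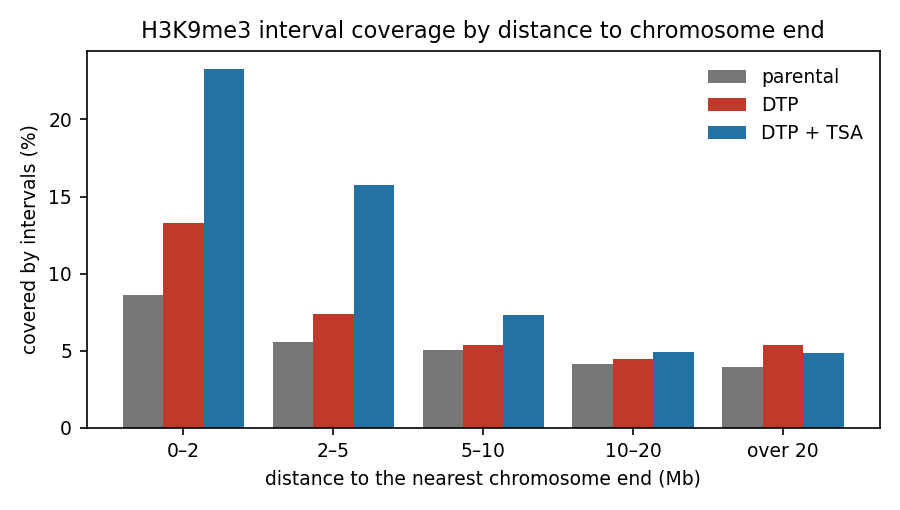
Percent of the genome covered by H3K9me3 intervals (vertical axis) by distance to the nearest chromosome end in Mb (horizontal axis), in the parental, DTP and DTP + TSA libraries, 1 bar per library. Within 2 Mb of an end coverage is 8.58%, 13.3% and 23.3%, and beyond 20 Mb it is 3.93%, 5.38% and 4.86%.

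By chromosome, coverage rose with TSA on 18 and fell on 6. Chromosome 22 had 2.13 times the DTP covered length, chromosome 17 1.67 times and chromosomes 16 and 20 had 1.504 and 1.502 times. Chromosome X, which had gained most in DTP, had 0.77 times, chromosome 4 0.88 times and chromosome 3 0.89 times. Dark bands fell, to 0.74 times in gpos100 and 0.83 times in gpos75, centromeric bands to 0.86 times, and light bands rose 1.26 times. The largest losses by band were smaller than the gains, with 11p11.12 from 28.7% to 21.7%, Xq11.1 from 12.1% to 6.86%, Xp11.21 from 18.1% to 13.0%, 19q11 from 19.4% to 14.6% and 4q23 from 10.5% to 6.73%.

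The 3 longest intervals found after TSA and not in DTP lay at chr22:47041601-47078000 in 22q13.31 (36.4 kb), chr8:145530401-145566800 in 8q24.3 (36.4 kb) and chr9:139388401-139418600 in 9q34.3 (30.2 kb). The 3 longest found in DTP and not after TSA were shorter, at chr12:38042201-38060400 in 12q11 (18.2 kb), chr9:68989001-69003200 in 9q21.11 (14.2 kb) and chr3:160301001-160313000 in 3q25.33 (12 kb).

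The third comparison asked whether persisters given TSA went back to the parental pattern. They did not do so in total, and dark bands came nearest to it. Coverage of gpos100 bands was 2.78% in parental cells, 4.36% in DTP and 3.22% in DTP + TSA, and that of gpos75 bands 3.58%, 4.67% and 3.86%, while light bands moved further away at 4.63%, 6.09% and 7.69%. DTP + TSA had 2.22 times as many intervals as parental cells and 1.43 times the covered length, and was covered more on all 24 chromosomes. With equal numbers of the strongest intervals by mean signal its covered length was 0.68 times the parental one, where the mean lengths of the full lists give 0.64. Of the 31488 DTP intervals absent from parental cells 20157 or 64.0% (63.5 to 64.5) still overlapped an interval after TSA, and of the 16378 shared with parental cells 14106 or 86.1% (85.6 to 86.7) did. Of the 8552 parental intervals lost in DTP, 1556 or 18.2% (17.4 to 19.03) overlapped DTP + TSA. Under local shifts of the DTP + TSA library these shares were 11.6%, 19.7% and 14.6%, so the return of lost parental intervals was little above that of their surroundings. In covered length, 52.4 Mb was present in all 3 libraries, 61.2 Mb in DTP and DTP + TSA only, 40.6 Mb in DTP only and 8.86 Mb in parental and DTP + TSA only. The DTP library enters both steps, so an interval missed or called there by chance looks like a change that was undone.

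Direct overlap of parental and DTP + TSA intervals was close to that of parental and DTP. Of the parental intervals 62.4% (61.7 to 63.0) overlapped DTP + TSA, and 30.5% (30.1 to 30.9) of the DTP + TSA intervals overlapped parental ones, against 13.9% and 7.02% under random rotation and 17.7% and 9.33% under local shifts. The bands that lost most in DTP stayed low after TSA, with 19p12 at 54.9%, 8q24.21 at 6.04% and 3q28 at 6.33%. The longest interval absent from DTP + TSA was the 3q28 one named above, followed by chr2:224386401-224419600 in 2q36.1 (33.2 kb) and chr11:122052401-122082000 in 11q24.1 (29.6 kb). The longest found in DTP + TSA and not in parental cells lay at chr2:241670401-241733200 in 2q37.3 (62.8 kb), chr12:34480801-34542200 in 12p11.1 (61.4 kb) and chr8:143197801-143253400 in 8q24.3 (55.6 kb).

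Centromeric bands were over-represented among the strongest intervals of each library, and the longest parental intervals lay mostly on chromosome 19. In parental cells the highest mean signal, 2911, was at chr1:121474001-121485600, against a library median of 8.22. This interval lies in 1p11.2, a light band beside a centromeric one, and its locus ranked 2 in DTP and 1 in DTP + TSA. Since the input libraries were not analysed here, reads piling up in repeats could not be told apart from the mark at such loci. Of the 100 intervals with the highest mean signal, 17 in parental cells, 18 in DTP and 14 in DTP + TSA lay in centromeric bands, which held 1.61%, 1.70% and 1.48% of all intervals. Of the 10 longest intervals, 9 in parental cells, 4 in DTP and 5 in DTP + TSA lay on chromosome 19. The longest of all spanned 271 kb in parental cells and 205 kb in each of the other libraries. The mean of the authors' mean signal over intervals was 11.3, 13.9 and 15.6, and these values are not on a stated common scale.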

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

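Recomputing 68 results under up to 11 alternatives gave 281 values, of which 164 stayed close to the reported value, 84 moved further and 33 changed direction. 3 of the alternatives, ranking by summit height, leaving out centromeric, variable and stalk bands, and leaving out 19p12, were chosen after seeing the data. For the changes below the cause was not tested, except that a stricter overlap rule counts fewer shared intervals by construction. Depth is unknown and may differ between libraries, which limits each comparison of counts and covered length, and leaves the size of the total change from parental to DTP open. DTP intervals were shorter on average than parental ones, so with equal numbers a ratio below 1 was nearly fixed. The mean lengths of the full lists give 0.66 for DTP over parental, against 0.71 found. No paired analysis was possible because each group has 1 library. The settings fixed beforehand for gene bodies, promoters and chromosome-matched gene sets were not run, since no hg19 annotation was used here.

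The overlap shares are given in the order DTP intervals in parental, DTP + TSA in DTP, DTP + TSA in parental, and DTP intervals absent from parental in DTP + TSA. They were 30.1%, 62.8%, 26.9% and 60.1% when at least 50% of the interval had to be covered, and 20.9%, 52.9%, 18.1% and 52.6% with reciprocal overlap of 50%. Joining intervals within 5 kb gave 34.7%, 68.4%, 31.5% and 65.3%. The upper part of each library by mean signal gave 31.3%, 59.3%, 28.1% and 56.7%, and equal numbers by mean signal 43.3%, 61.4%, 37.7% and 52.9%. Equal numbers by summit height gave 47.0%, 66.9%, 41.1% and 59.4%. Without intervals below the pooled median length they were 41.4%, 65.8%, 38.4% and 58.2%. On autosomes the first 2 were 34.9% and 65.8%, and without centromeric, variable and stalk bands the first 3 were 33.8%, 65.8% and 29.9%.

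With equal numbers by mean signal, covered length was 0.71 times for DTP over parental, 0.96 times for DTP + TSA over DTP and 0.68 times for DTP + TSA over parental, and DTP over parental was 0.93 on chromosome X, 0.82 on chromosome 4, 0.62 on chromosome 19, 0.89 within 5 Mb of an end, 0.85 in 19q11, 0.76 in 12p11.1 and 0.43 in 11p11.12; the last 3 stayed above 1 by summit height, at 1.87, 1.11 and 1.23. With equal numbers by summit height it was 0.83 over all chromosomes, 0.96 on X and 0.95 on chromosome 4, and DTP + TSA over parental was 0.84. Chromosome 19 was at 0.71 in the upper part by mean signal, 0.78 with equal numbers by summit height, 1.03 after joining, 1.11 without 19p12 and 1.09 without centromeric, variable and stalk bands, which include 19p12. In the upper part by mean signal Xp11.21 was at 15.8 and 12p11.1 at 3.58. The DTP over parental ratio of interval numbers was 1.33 without short intervals, and that of DTP + TSA over parental 1.40. The ratio of 6 kb to 5 kb intervals in DTP was 1.82 after joining, 1.66 in the upper part by signal, and 1.67 and 1.55 with equal numbers by mean signal and by summit height; in DTP + TSA it was 0.96 with equal numbers by mean signal and 1.65 after joining.

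The band coverage of gene lists with equal numbers changed from parental to DTP by -8.70 points for zinc finger genes, -1.30 for olfactory receptors, -2.89 for clustered protocadherins, -0.38 for cancer-testis antigens, -0.70 for HOX clusters, -2.09 for histone genes, -1.64 for imprinted genes, -1.22 for the H3K9 machinery, -0.65 for interferon genes, -1.83 for the EGFR list, -1.40 for demethylases and deacetylases, -0.76 for lung genes, -0.99 for other lineages, -0.75 for long neuronal genes and -1.28 for housekeeping genes. From DTP to DTP + TSA it changed by 1.08 for zinc finger genes, -0.39 for HOX clusters and -0.043 for histone genes. The other rises were 1.68 for imprinted genes, 1.43 for demethylases and deacetylases, 1.29 for housekeeping genes, 0.57 for the H3K9 machinery and 0.42 for other lineages. They were 0.41 for the EGFR list, 0.20 for interferon genes, 0.15 for olfactory receptors and 0.12 for both lung genes and clustered protocadherins. Each rise was smaller than with all intervals. Cancer-testis antigens changed by -0.41 and long neuronal genes by -0.18. Without 19p12, with all intervals, the zinc finger change from parental to DTP was 0.15.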

Other observations

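Of the tests below, those of gene density, of zinc finger clusters and of chromosome 19 bands were chosen only after the values they use had been seen; the others were set before. The losses in single regions were clustered. Of the 8 windows of 1 Mb that lost most coverage from parental cells to DTP, 4 lay on chromosome 19 between 20 and 24 Mb, 2 on chromosome 7, 1 on chromosome 3 and 1 on chromosome 8. On chromosome 7, chr7:63000001-64000000 went from 68.1% to 30.0% and chr7:41000001-42000000 from 42.3% to 7.96%.

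A hypothesis for the 6 kb class in DTP is H3K9me3 over full-length LINE-1 elements. These are about that long and concentrate in dark bands and on chromosome X. DTP + TSA had the class too, with a local maximum at 6 kb, and a ratio of 1.65 with intervals within 5 kb joined. In DTP the share in dark bands exceeded that of flanking lengths by 8.93 points, as the hypothesis would require. The share on chromosome X, 5.02% (4.15 to 6.002) against 3.56% (2.89 to 4.34), could not be separated by its intervals. It was no higher than the 5.10% of all DTP intervals. Among the 23842 strongest DTP intervals the ratio of 6 kb to 5 kb intervals was 1.67 (1.52 to 1.83), against 0.69 in parental cells. This argues against weaker intervals, admitted by a lower calling threshold in DTP, as the source of the class. The ranking keeps the called borders, so an effect of the threshold on interval lengths stays open. Other repeats of about 6 kb, read mapping in repeats and a difference between the single libraries stay open, since repeat positions were not used here.

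The gain toward chromosome ends with TSA may follow sequence or library bias toward gene-dense DNA: away from ends the DTP + TSA over DTP ratio was 1.51 times higher in the most gene-dense bands than in the least dense ones, with bands split into 3 classes of gene density. Nearness to an end met its own test as well, since in the least dense bands the ratio was 1.56 times higher within 10 Mb of an end, over 32 bands, so gene density and nearness both stay open. Weaker intervals, admitted by a lower threshold in DTP + TSA, are argued against as its source. With equal numbers of the strongest intervals the ratio within 5 Mb of an end was 2.26 times that beyond 10 Mb. These intervals keep their called borders, so a threshold effect on their lengths stays open. An effect of TSA and a difference in GC bias or background between the 2 libraries stay open and were not tested.

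A loss of broad covered windows in DTP depends on how windows of 1 Mb are chosen: DTP over parental was 0.99 over the 66 with a mean of at least 20% over the 3 libraries, a filter that also admits windows raised by TSA, and 0.84 over the 54 with that mean over parental and DTP, chosen after the data had been seen, so the test of sub-threshold gaps set before, 1.04 on the first set after joining intervals within 5 kb, decides nothing. Narrowed to the 6 zinc finger bands of chromosome 19 (0.82, and 0.88 after joining), the loss lay mainly in 19p12. There 0.62 rose only to 0.69, which argues against gaps of up to 5 kb as its whole cause. Wider gaps were not joined and stay open. The other 5 bands went from 0.95 to 1.01, so there gaps stay open. Fewer copies of chromosome 19 in the DTP library are argued against by the other bands of that chromosome, at 1.48. Whether the loss centred on chromosome 19 cannot be told apart from a wider one, since the windows elsewhere stood at 1.17 in the first set and 0.88 in the second. Of those elsewhere, 39 of 49 in the first set were higher in DTP. In the second set 21 were higher and 17 lower, so any loss elsewhere was not shared by most windows. Local copy number changes and a biological loss in persisters stay open.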
